A study of Homo sapiens with 3 samples.

How the data were processed

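Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map EP300, a histone acetyltransferase and transcriptional coactivator, in H9 cells. H9 is an established human embryonic stem cell line. Per the labels, the cells were wild type and held in a naive state in PXGL, a medium with inhibitors of MEK, tankyrase and protein kinase C and with LIF at 10 ng/mL, on a layer of mouse embryonic fibroblasts. Cells were crosslinked in 1% formaldehyde for 10 min and quenched in 0.125 M glycine for 5 min before sonication, per the labels' protocols. The series holds 2 EP300 samples and 1 input sample without antibody. Nothing in the labels says that the EP300 samples came from separate cultures, so the spread between them may be technical.

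The authors deposited 1 peak table for each EP300 sample, and peaks were therefore called per sample and not on pooled reads. By the names of the tables and of the peaks, both lists were called against input, and probably against the same input library. The input library has no table of its own and was not analysed here separately. The submitters' processing notes name fastp 0.19.11, with no role given, and the genome build GRCh38. The aligner, the peak caller, its threshold and the treatment of duplicate reads are not given in the sources used here. The peak positions were annotated with ChIPseeker, per the names of the deposited tables.

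Each deposited row is 1 summit, so a peak with several summits fills several rows. Per the file headers, each row has a signal value, which is the fold enrichment at the summit as the authors' caller gave it, a ratio. Per the file headers, each row also has a -log10 p-value and a -log10 q-value. The largest q in the deposited tables was 0.0497 in replicate 1 and 0.0498 in replicate 2. The deposited score column was 10 times the -log10 q-value in whole numbers and was not used. The fold enrichment is the authors' own value per peak and was used here only to describe, filter or rank peaks within a list. Read depth is unknown, because the tables hold no read counts.

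Rows of the same interval were joined and kept the highest fold enrichment, its summit and the highest -log10 q-value. Comparisons used chromosomes 1 to 22 and X. A peak was shared if it overlapped a peak of the other replicate by at least 1 bp, and each group of overlapping peaks of both replicates was merged into a reproducible region. The percentile of a region is the lower of its fold enrichment percentiles in the 2 lists. Chance overlap came from 100 circular shifts of replicate 2 along each chromosome. A stricter chance level moved promoter peaks to the 5' ends of random coding genes and shifted only the others. For genes without known strand, either end was taken at random.

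Genes were the 19974 protein-coding RefSeq genes of GRCh38.p14 on these chromosomes. The gene table used here has no strand, so strand was taken from the authors' annotation by name and overlapping position for 15465 genes. For the other 4509 genes both ends were examined, and 1040 genes whose ends differed were left out, which left 18934. A promoter was occupied if a reproducible region lay within 3 kb of the RefSeq 5' end. RefSeq gene extents include the longest transcript models, so this end can lie far from the start site in use. A distal region lay over 3 kb and up to 100 kb from the start site of the gene the authors assigned it to.

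The 16 gene lists, the 5 gene families, the tests, the windows and the rule for naming genes were fixed before the data were examined. Promoter occupancy was compared with all other coding genes by two-sided Fisher's exact tests. Distal regions per gene were compared with 10000 random lists matched on gene length and on the distance to neighbouring genes, by two-sided permutation p-values. Both were adjusted by Benjamini-Hochberg over the 21 lists and families, with a threshold of 0.05. The naive and primed lists were compared by Fisher's exact test for occupancy and by a permutation test with 100000 resamples for distal regions. Shares have Wilson 95% intervals, which cover counting error only. Genes and peaks are not independent replicates, so these p-values describe these lists and not a population of cultures.

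Genes named in the text are OGA, OGT and EP300, pluripotency list members without a region within 100 kb, up to 4 occupied members of each list by percentile, and the 2 members with most distal regions. The rule also takes the genes nearest the 10 highest-ranked promoter and distal regions, the 10 genes with most distal regions and the genes of the top 10 clusters. Other genes are named where a count is small and were then chosen after their values were seen. Some genes that the rule takes are not reported here.

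The list tests were checked on simulated data over 19974 genes. For occupancy, 99% of lists of 20 genes set to 30% occupancy were called, 84% of those set to 99%, and 3% of unchanged lists. Simulated genes were occupied independently of their neighbours, at a base rate somewhat above the observed one. These rates therefore do not cover clustered families, in which 1 region can serve several genes. For distal regions, 96% of lists of 20 genes with 3 times the counts plus 1 region per gene were called, and 2% of unchanged lists. Smaller rises were not simulated. In the overlap step, 100% of the copies planted among 20000 intervals were found. The copies were moved by less than their width, so this checked the code only. Alternatives were a 50% overlap of both peaks, a -log10 q-value of at least 5, a fold enrichment of at least 5, other windows, the authors' own gene assignment and the omission of either replicate. After seeing the data, occupancy by either the RefSeq end or the authors' assignment, other treatments of genes without strand, and the shared pluripotency list without its member with most distal regions were added. Motif searches at summits need a genome sequence and were not run. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.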

Results

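EP300 peaks were mapped by ChIP-seq in naive H9 human embryonic stem cells in 2 samples of 1 group, with 1 input sample. After joining summits, replicate 1 held 65276 peaks and replicate 2 held 64896 on chromosomes 1 to 22 and X. The median peak was 748 bp wide in replicate 1 and 781 bp in replicate 2. Peaks covered 63.4 Mb and 65.7 Mb, with a median fold enrichment of 4.51 in both lists. Read depth is unknown, so its effect on the number of peaks could not be assessed.

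The first comparison asked how far the 2 EP300 maps matched. In replicate 1, 74.5% of peaks overlapped a peak of replicate 2 (Wilson 95% interval 74.2 to 74.8), and 73.9% of replicate 2 peaks overlapped one of replicate 1 (73.6 to 74.2). Both values describe the same pair of lists, counted from each side, and their mean was 74.2%. Circular shifts gave 4.50%, so the overlap was 16.5 times chance, and none of the 100 shifts reached it (smallest permutation p possible, 0.0099). A stricter chance level, with promoter peaks moved between coding genes, gave 17.2%, and the overlap was 4.34 times that. This level used either end of genes without known strand and no non-coding start sites, so it may be too low. The shared peaks formed 46263 reproducible regions with a median length of 1114 bp, and the summits of both replicates lay a median of 59 bp apart. Part of this excess may come from an input library used for both lists.

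The strongest sites were found in both replicates almost without exception. In the highest decile by fold enrichment, 6528 of 6528 peaks of replicate 1 and 6489 of 6490 peaks of replicate 2 were shared. In the lowest decile the shares were 44.2% and 41.4%. The most enriched promoter regions lay at IL27RA, a cytokine receptor gene (chromosome 19, 14030910 to 14032751, fold enrichment 36.2 and 39.2 in replicates 1 and 2), and at EMB (chromosome 5, 50440245 to 50441772, 36.0 and 38.5). RBM43, CACNB4, TEX10, ANO2, PRELID3A, EPDR1 and ERAP1 were also among the 10 highest promoter regions. The most enriched region of all was intronic, at 68919637 to 68922332 on chromosome 5, with fold enrichment 52.5 and 45.8. Its nearest annotated gene was ENSG00000250066. Other leading distal regions lay nearest SORBS2, PTPRN2, SCOC, NPM1P6 and C5orf64.

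**Figure D1:**
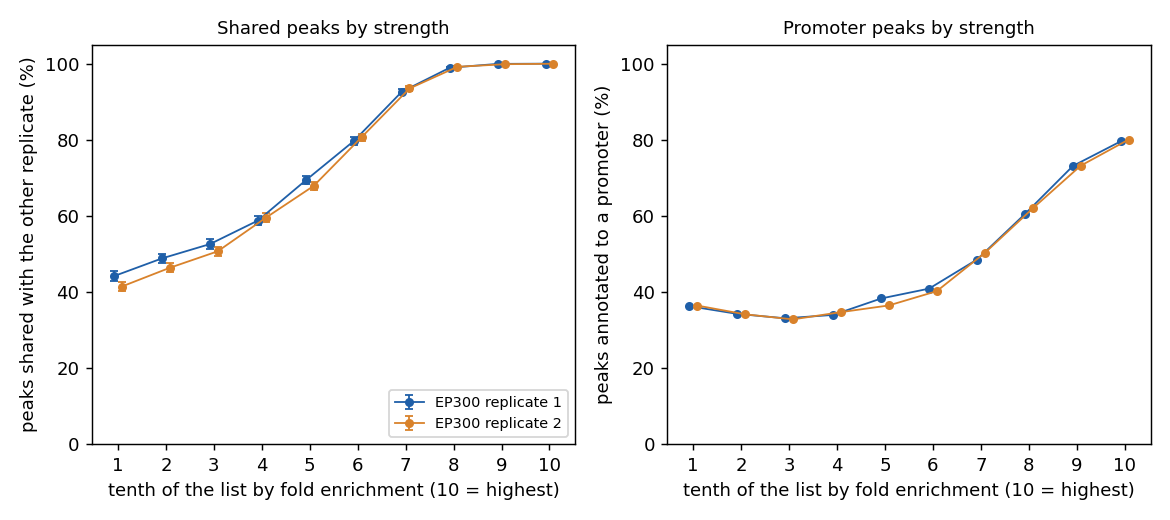
Left, percent of peaks shared with the other replicate (y axis) by decile of the list ranked by fold enrichment (x axis), with Wilson 95% intervals, for EP300 replicate 1 (blue) and replicate 2 (orange). Right, percent of peaks annotated to a promoter for the same deciles, which was 79.6% in the highest decile of replicate 1.

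EP300 peaks lay mostly at promoters, in intergenic DNA and in introns. The authors' annotation placed 47.9% ± 0.12 (SD, n = 2) of peaks in promoters, 24.0% ± 0.19 in distal intergenic DNA and 22.3% ± 0.03 in introns. Promoter peaks were also the stronger class, with a median fold enrichment of 5.67 in replicate 1 and 5.71 in replicate 2, against 4.09 and 4.13 for distal intergenic peaks. In replicate 1, 54.1% of shared peaks and 29.7% of peaks seen in that replicate alone were promoter peaks (odds ratio 2.79, 95% interval 2.69 to 2.90). In replicate 2 the shares were 54.1% and 30.7% (odds ratio 2.67, 2.57 to 2.77). Intron peaks went the other way, with 18.8% of shared and 32.7% of unshared peaks in replicate 1 (odds ratio 0.474, 0.456 to 0.493). Among reproducible regions, 36.9% overlapped an annotated start site and 45.8% lay over 3 kb from one, at a median of 14.2 kb.

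The series concerns O-GlcNAcase, the enzyme that removes O-GlcNAc from proteins, and its title raises the question whether EP300 lies at the OGA gene. A reproducible EP300 region covered the OGA promoter. Such regions were common, within 3 kb of the 5' end of 72.2% of the coding genes tested. The median percentile of occupied promoters was 79.7. OGA lies on the minus strand of chromosome 10 at 101784450 to 101818444 (GRCh38). Its promoter peak spanned 101817442 to 101818503 in replicate 1, with fold enrichment 11.2 and a -log10 q-value of 39.4, at percentile 89.8 of that list. In replicate 2 it spanned 101817522 to 101818470, with fold enrichment 14.0 and a -log10 q-value of 54.2, at percentile 94.2. Within 50 kb of OGA there were 9 reproducible regions, and within 10 kb there were 5. The others were assigned to the neighbouring genes FGF8, NPM3, KCNIP2-AS1 and KCNIP2. No peak in either list lay within the OGA gene body outside this promoter peak.

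**Figure D2:**
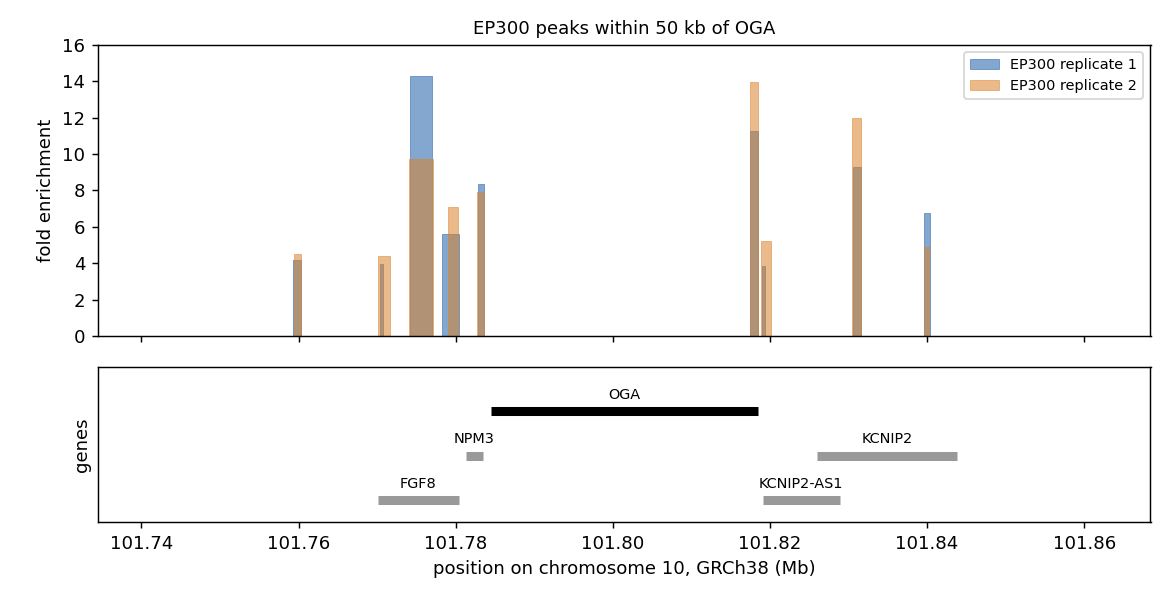
Peaks within 50 kb of OGA on chromosome 10, drawn at their positions (x axis, Mb, GRCh38) with the authors' fold enrichment (y axis) for EP300 replicate 1 (blue) and replicate 2 (orange), above the RefSeq extents of the genes. The peak at the right end of OGA, its promoter, reached 11.2 and 14.0.

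OGT, the gene of the opposing transferase that adds O-GlcNAc, carried a weak promoter peak in replicate 1 alone, with fold enrichment 4.34 at percentile 47.0. It lies on the X chromosome, where 49.5% of coding promoters were occupied, against 73.2% on autosomes. Of the O-GlcNAc and hexosamine pathway list, 13 of 14 genes had an occupied promoter (92.9%, 68.5 to 98.7; Fisher's exact test, adjusted p = 0.198). GFPT1, which catalyses the entry step of the hexosamine pathway, led the list with fold enrichment 14.7 and 17.6, and NPL, PGM3 and AMDHD2 followed. GFPT2 and NAGK had most distal regions in the list, 6 and 5. EP300 lay at its own promoter, at percentiles 92.4 and 93.6 of the lists of replicates 1 and 2.

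Across all coding genes, 13668 of 18934 promoters (72.2%) were occupied. Some of the fixed lists and families stood above this level. All 24 housekeeping genes tested (adjusted p = 0.0028), 17 of 17 ERK response genes (adjusted p = 0.013) and 73 of 78 ribosomal protein genes (adjusted p = 1.26e-05) were occupied, each by Fisher's exact test. Occupied ERK response genes included the phosphatase genes DUSP6, with fold enrichment 28.9 and 35.0, and DUSP4, with 24.6 and 25.2, then CCND1 and FOSL1. YWHAZ, GAPDH and PPIA were among the highest-ranked housekeeping genes. The ERK response call was lost with a window of 10 kb (exact test, adjusted p = 0.0574) and with a 50% overlap (adjusted p = 0.185).

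Of the coactivators and acetyltransferases, 19 of 20 promoters were occupied (exact test, adjusted p = 0.0467), led by CITED2, with fold enrichment 30.4 and 26.0, KAT2A, KAT5 and EP300 itself. This call was lost without replicate 1 (exact test, adjusted p = 0.0725), without replicate 2 (adjusted p = 0.0662) and with a 50% overlap (adjusted p = 0.0969). It was also lost with genes of undecided strand counted as occupied (exact test, adjusted p = 0.0798). Zinc finger ZNF genes were occupied at 409 of 482 promoters (exact test, adjusted p = 2.97e-10). Replication-dependent histone genes were occupied at 54 of 61 (exact test, adjusted p = 0.0098). These genes are short and clustered, so 1 region can count for several of them. H3C8 and H2BC10, the highest-ranked, shared 1 region (chromosome 6, 26271800 to 26272683). The exact test treats such genes as separate, so its p-value overstates the evidence. The histone call turned to lower occupancy, 54.0%, with the authors' own assignment, in which each peak has 1 gene (exact test, adjusted p = 0.0261). At a fold enrichment of at least 5 it was lost and turned direction, with 56.7% against 58.0% of all coding genes (exact test, adjusted p = 0.941). It was also lost within 1 kb (exact test, adjusted p = 0.682) and at a -log10 q-value of at least 5 (adjusted p = 0.0631).

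**Figure D3:**
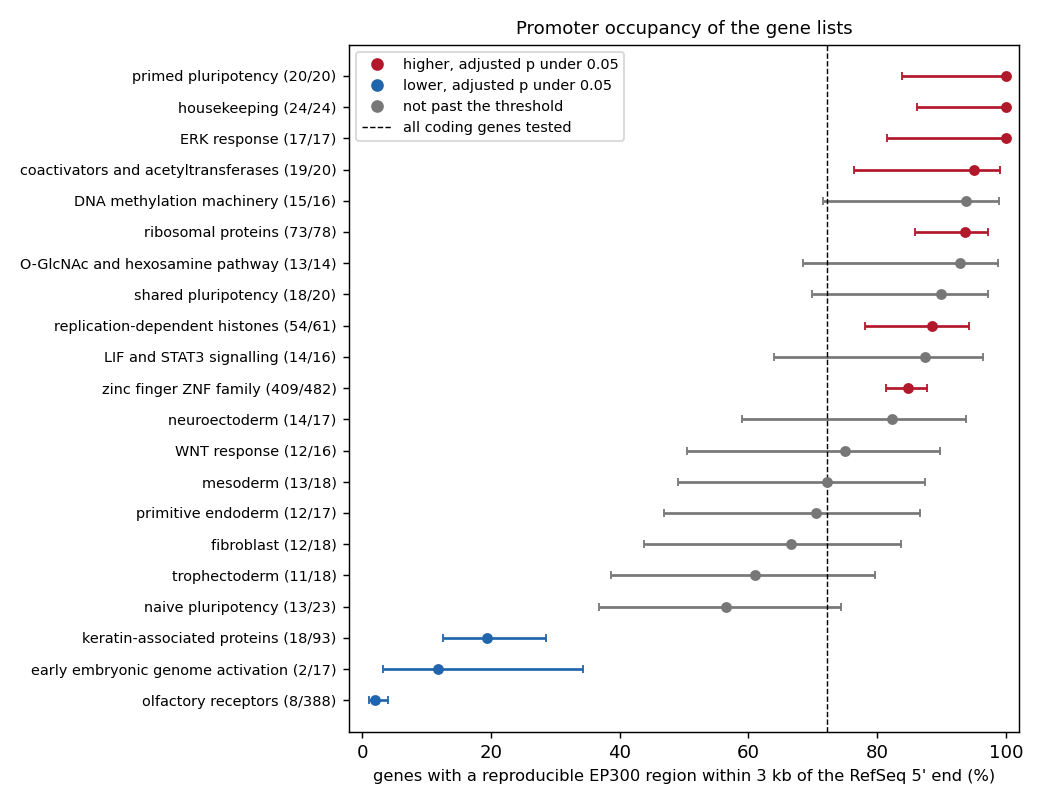
Percent of genes of each list with a reproducible EP300 region within 3 kb of the RefSeq 5' end (x axis), with Wilson 95% intervals and the counts in brackets. Red lists were higher and blue lists lower than all other coding genes by Fisher's exact test with adjustment over 21 lists, and the dashed line marks all coding genes, 72.2%.

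Gene families that are silent in most tissues were rarely occupied. Only 8 of 388 olfactory receptor genes (2.06%; exact test, adjusted p = 5.29e-200) and 18 of 93 keratin-associated protein genes (19.4%; adjusted p = 3.61e-25) had an occupied promoter. Genes of early embryonic genome activation were also low, with 2 of 17 (exact test, adjusted p = 1.78e-06). These were RFPL2, with fold enrichment 5.79 and 8.88, and ZSCAN4, with 3.70 and 3.75. Several of these genes belong to multicopy families, TRIM49, MBD3L2 and PRAMEF1 among them, where short reads may not map to 1 place.

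Genes of the primed state, the later pluripotent state that follows the naive one, were occupied in full. All 20 of 20 primed pluripotency genes had a promoter region (exact test, adjusted p = 0.0061), led by the transcription factor genes HMX2, with fold enrichment 25.8 and 25.2, and TCF7L1, with 27.3 and 22.1, then by SFRP2 and PTPRZ1. The homeobox gene OTX2 reached 23.5 and 20.1. Of the naive pluripotency list, 13 of 23 genes (56.5%, 36.8 to 74.4) were occupied (exact test against all other genes, adjusted p = 0.169). TFAP2C, a transcription factor gene of the naive state, was the highest at 22.4 and 27.1, followed by DNMT3L, KLF4 and DPPA5. ZNF729 was the 1 naive gene without a reproducible region within 100 kb.

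The naive list was occupied 43.5 percentage points less than the primed list (Fisher's exact test, p = 0.000693). KLF17 and KLF5 counted as unoccupied because their RefSeq ends lie away from the start sites in the authors' annotation, where both had a reproducible region. With either kind of start site accepted, 65.2% of naive genes were occupied, and the difference from the primed list was 34.8 points (exact test, p = 0.00425). The difference in distal regions did not pass its test, at 0.61 ± 0.94 (SD, n = 23) per naive gene and 0.75 ± 1.16 (SD, n = 20) per primed gene (permutation p = 0.778). DPPA3 had 3 distal regions, the most in the naive list, and CD24 had 5, the most in the primed list.

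Of the shared pluripotency list, which holds genes used in both states, 18 of 20 promoters were occupied (exact test, adjusted p = 0.146). LIN28A ranked highest with fold enrichment 21.0 and 23.9, followed by PRDM14, TERT and POU5F1. The exceptions were LIN28B and NODAL, which both had a reproducible region at the start site in the authors' annotation, NODAL with fold enrichment 25.9 and 28.0. With the authors' own assignment all 20 were occupied (100%; exact test, adjusted p = 0.00292).

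The shared pluripotency list was the 1 list with more distal regions than matched random lists, at 3.58 times their mean of 0.363 per gene (permutation test, adjusted p = 0.0308). PODXL, a sialomucin gene, held 13 of the list's 26 distal regions, and LEFTY1 held 3. Without PODXL the mean was 0.684 and the call was lost (permutation test, adjusted p = 0.357), as it was without replicate 1 (adjusted p = 0.202), with a 50% overlap, with either stricter filter and with unmatched lists. Olfactory receptor genes had fewer distal regions than matched lists, 0.0308 against 0.177 per gene, and ZNF genes likewise, 0.173 against 0.344 (permutation test, adjusted p = 0.0021 each). The ZNF call was lost at a fold enrichment of at least 5 (permutation test, adjusted p = 0.0693). No other list passed this test. Its power for rises smaller than those simulated is unknown.

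No list of markers of other lineages passed the test of promoter occupancy. Occupied were 11 of 18 trophectoderm genes (exact test, adjusted p = 0.392), 12 of 17 primitive endoderm genes (adjusted p = 1), 13 of 18 mesoderm genes (adjusted p = 1), 14 of 17 neuroectoderm genes (adjusted p = 0.53) and 12 of 18 fibroblast genes (adjusted p = 0.703). Strong promoter regions were nonetheless present in these lists, at KRT7 and TEAD3, at the basement membrane genes NID2 and LAMB1, at MESP2 and WNT3, at TUBB3, and at MMP2 and COL1A2. MESP2 reached fold enrichment 24.8 and 26.2, and NID2 25.6 and 22.2. Among signalling lists, 14 of 16 LIF and STAT3 genes (exact test, adjusted p = 0.369), led by JAK2 and JAK1, and 12 of 16 WNT response genes (adjusted p = 1), led by CCND1 and BMP4, were occupied. DNA methylation genes were occupied at 15 of 16 promoters (exact test, adjusted p = 0.104), with UHRF2, GADD45A, DNMT1 and TET1 highest, and at all 16 with the authors' own assignment (adjusted p = 0.00995).

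Distal EP300 regions were spread widely, with 21176 reproducible regions over 3 kb from a start site and 4082 coding genes with at least 1 distal region. RBFOX3, a neuronal splicing factor gene, had the most, 28, followed by TCERG1L-AS1 with 24, CASZ1 with 23, SHANK2 with 20 and SDK1 with 19. These counts were not matched on gene length or on the distance to neighbouring genes. Neighbouring regions, promoter regions included, were stitched into 25251 clusters at a main distance of 2.5 times 5 kb. Of these, 16950 were single regions and 318 held 10 or more regions, or 56 with a stitching distance of 5 kb. At the main distance the largest held 37 regions over 198 kb of chromosome 9 (135215662 to 135413759), around non-coding genes, at a median percentile of 29.5. The next, with 36 regions on chromosome 22 (45866534 to 46086503), covered WNT7B and MIRLET7BHG. Others of the top 10 lay at GATA5 and MIR1-1HG, at GSE1, at IRF2BPL, at NACC2 and LHX3, at KCNQ1 and CDKN1C, at PODXL, at GADD45G and at PTP4A3. This ranking depends on the distance: at 5 kb the largest held 18 regions, on chromosome 9 (136544166 to 136627326) at NOTCH1 and NALT1. Of the loci in the top 10 at the main distance, only PODXL and GSE1 were in the top 10 at 5 kb.

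Reproducible regions were densest on chromosome 19, with 41.1 per Mb, followed by chromosome 17 with 31.3 and chromosome 22 with 26.8. Length was taken as the last annotated position, unassembled stretches included. On this measure chromosome 13 had the lowest density, 8.60 per Mb, followed by the X chromosome with 9.30. Per coding gene the order differed, with 1.66 regions on chromosome 19, the fewest, 1.71 on the X chromosome and 2.91 on chromosome 13. Promoter occupancy on the X chromosome was 49.5% of 822 coding genes, against 73.2% of 18112 autosomal genes (Fisher's exact test, added after seeing the data, p = 7.52e-45).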

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

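The test of peak strength below was chosen after its result was seen, and the others were written beforehand. Peaks on unplaced sequences, which entered no comparison, numbered 45 in replicate 1 and 42 in replicate 2. They were flagged by a fixed floor of 3 peaks, with no expected number to set them against. The sequences with most such peaks in replicate 1 were KI270733.1 (10 and 7), which carries an annotated RNA5-8SN4 gene, GL000220.1 (7 and 6) and KI270713.1 (7 and 6), with the count in replicate 2 given second. The highest fold enrichment there was 18.6 in replicate 1 and 15.4 in replicate 2, on GL000195.1.

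Of the peaks in replicate 1, 16649 had no counterpart in replicate 2. A threshold on weak signal is consistent with this, since 88.7% of them lay in the lower part of the list, below the median fold enrichment, and 0.378% of the peaks above percentile 70, with ties given their mean rank, were unshared (74 of 19580). A shifted position of the same site remains open, because 24.6% of the unshared peaks had a replicate 2 peak within 1 kb against 7.24% by chance. That share lies between the bounds set beforehand, so the test did not decide. Depth differences were not tested, because the tables hold no read counts, and the design gives no biological explanation to test.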

How the results depend on the processing

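Of the settings tried, 41 values that answer a comparison stayed within their limits and 10 moved, with single lists counted apart below. None of these values past its threshold turned direction. The distal difference between the naive and primed lists, never past it, ranged from -0.330 to 0.248 regions per gene. The mean shared percentage was 63.2 with a 50% overlap, 80.1 with a -log10 q-value of at least 5 and 83.8 with a fold enrichment of at least 5. Overlap over chance was 4.34 with promoter peaks moved between coding genes. The promoter share was 57.7% at the stricter q, 64.6% at the stricter fold and 37.9% within 1 kb. At the stricter fold 1 list passed the distal test, against 3. Within 10 kb of OGA there were 5 regions, and 56 clusters at 5 kb. The filters kept 62.2% and 42.1% of replicate 1 peaks, and a stricter overlap or narrower window admits fewer peaks by construction.

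The naive list stayed below the primed list in all 9 alternatives, by 34.8 to 56.5 points (exact test, p from 3.34e-05 to 0.00498). Between 8 and 12 lists passed the occupancy test. Of the values for single lists, 354 stayed called or stayed uncalled, 14 lost a call and 7 gained one. A turn of direction was counted only where the list passed in the main or the other setting, and 3 values turned so. Those were the histone promoters, 56.7% at the stricter fold and 54.0% with the authors' assignment, and the histone distal ratio, 0.226 with unmatched random lists. The cause was not tested. Naive occupancy fell below other genes at the stricter q (43.5%; exact test, adjusted p = 0.0493). Acceptance of either start site, the treatment of genes without strand, and 1 kb or the authors' assignment for the naive and primed lists were chosen after seeing the data. No paired analysis was possible because only 1 group has more than 1 sample. The planned motif tests were not run, for want of a genome sequence. Depth is unknown, so a missing peak is not evidence of absent EP300.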

Other observations

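The tests of symbol families and of promoter strength, and the test without near-identical copies, were chosen after results were seen, and the other tests were written beforehand. Coding genes were grouped by the letters that open their symbol, which gave 253 families of at least 10 tested genes. By Fisher's exact test with adjustment over these families, 19 were occupied more often and 45 less often than other genes. All 19 SOX genes (adjusted p = 0.0172) and all 43 genes with RPS symbols (adjusted p = 1.66e-05), which include ribosomal S6 kinases, had an occupied promoter (Fisher's exact test). In contrast, 0 of 10 HOXA genes (0%, Wilson upper bound 27.7; adjusted p = 3.48e-05) and 2 of 10 HOXB genes (adjusted p = 0.00549) did, by the same exact test. Beta-defensin (DEFB, 0 of 39), PRAMEF (0 of 23) and interferon alpha (IFNA, 0 of 13) genes were also unoccupied, and these are multicopy families. No family had more distal regions than matched lists after adjustment. The WNT genes came closest, with 1.53 against 0.408 per gene (permutation test, adjusted p = 0.0675).

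Among occupied promoters, the primed list was stronger than random occupied promoters, with a median percentile of 91.5 against 79.7 (permutation test, adjusted p = 0.0133). The neuroectoderm list was weaker, at 47.8 (permutation test, adjusted p = 0.008). TUBB3 was its strongest member, with fold enrichment 17.9 and 15.1. Occupied histone (69.0; adjusted p = 0.018), olfactory receptor (44.9; adjusted p = 0.0208) and keratin-associated protein promoters (44.1; adjusted p = 0.004) were also weaker in the permutation test. The naive list stood at 61.4 and did not pass (permutation test, adjusted p = 0.056). Its occupied promoters averaged 58.4 ± 23.6 (SD, n = 13), against 84.1 ± 16.8 (SD, n = 20) in the primed list (permutation p = 0.0015).

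The lower occupancy of the naive list than of the primed list, in cells grown as naive, was weighed against properties of the genes. Gene length and spacing do not account for it: the occupancy of genes matched to the primed list minus that of genes matched to the naive list was -0.0511 points. ALPP, ALPG, KHDC1L, ZNF729, TRIM60 and NLRP7 were taken to have near-identical copies, without a measure of sequence identity. Without them, 64.7% of naive promoters were occupied (11 of 17, Wilson interval 41.3 to 82.7), under the 90% that copies would require as the whole cause. Copies as part of the cause are not excluded by this. KLF17 and KLF5 still counted as unoccupied here, and copies and start sites were not weighed together. Start site choice remains open in part, since acceptance of either start site moved the difference from 43.5 to 34.8 points. The base composition of the promoters and the expression of the genes were not tested, so no biological explanation was tested.

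The lower occupancy of X promoters was weighed as well. Multicopy families do not account for it: without uncharacterised genes and genes of large symbol families, X occupancy was -24.0 points relative to autosomes (95% interval -28.1 to -20.0), against -23.7 with all genes. Occupied X promoters were also weaker, by a median of -23.3 percentile points (bootstrap interval -26.6 to -19.5). A generally weaker enrichment at X promoters requires this. Only occupied promoters were ranked, so enrichment over the whole chromosome was not tested. Distal regions numbered 5.04 per Mb on the X chromosome, above chromosomes 13 (4.70) and 4 (4.90) and below every other autosome. X promoter occupancy was below that of every autosome, the lowest of which was chromosome 21 with 62.6%. The lower occupancy may come from fewer X promoter peaks reaching the calling threshold. The origin of the weaker signal at X promoters cannot be resolved without read counts. No biological explanation was tested.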
